A study of Mus musculus with 3 samples.

How the data were processed

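Single wells of adult mouse heart cells were profiled on the iCELL8 platform, in which cells are dispensed into nanowells and imaged, and wells holding a single Hoechst-positive, propidium iodide-negative cell are taken into reverse transcription and amplification. Per the labels, the polyA RNA came from adult cardiomyocytes of tamoxifen-treated mice, tagmented libraries were made with the Nextera XT kit, and paired-end reads were made on a NovaSeq instrument. The samples used here were 3 libraries, taken after 1, 2 and 3 days. Day 0, which the series design also names, was not analysed here.

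The deposited tables hold raw read counts per gene and well barcode, as whole numbers with no normalization. Per the submitters' processing notes, the tools were cutadapt, STAR and featureCounts with the genome build mm10; their versions, the strand setting, the annotation and any collapsing of duplicate molecules are not given in the sources used here. Counts are therefore treated as reads, and each interval below covers counting error only, because reads without molecular identifiers are not independent molecules. The deposited count tables have 55502 features, of which 55401 are mouse gene identifiers, 92 are ERCC spike-ins, 7 are SIRV spike-ins and 2 are added sequences, EGFP and 3xFlag. Gene symbols and coordinates were taken from GENCODE release M21 on mm10, where 55141 identifiers were found, 54349 of them with the same version; the other identifiers have no symbol here. The barcode lists match the columns of the tables in every library and carry no well annotation beyond the barcode, so no file assigns day 3 wells to a genotype.

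Wells with at least 1000 counts and at least 300 detected genes were kept, which left out 18 wells over the 3 libraries. Kept wells of all libraries were clustered together without integration in scanpy 1.11.5 with anndata 0.12.19 and igraph 0.11.9: counts were scaled to 10000 per well and log-transformed, 2000 variable genes and 30 principal components were used, neighbourhoods had 15 neighbours, and Leiden clustering was run at resolution 0.5 with the random seed 0. A cluster was given the name of a cell type when at least 3 of that type's fixed markers were at least 2-fold above the other wells at 20 CPM or more and its 10 leading genes did not go against the name. Marker lists were fixed in advance, whereas these thresholds were set after an exploratory clustering with the same parameters had been seen. Doublets were not called: per the labels wells were chosen by imaging, and no doublet caller was run here. Other classes rebuilt from the same tables with another rule would differ.

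Comparisons used the cardiomyocyte compartment, defined by exclusion as kept wells outside clusters named as a non-cardiomyocyte type, with atrial-like wells kept in, because the labels call the material adult cardiomyocytes. Compartment wells are therefore not shown to be cardiomyocytes by markers. Raw counts were summed per library and divided by the total over nuclear-encoded genes to give CPM, the counts per 1000000 such counts, because the mitochondrial share varied between libraries. CPM values have exact Poisson 95% intervals, log2 ratios of 2 libraries have exact 95% intervals from the binomial split of the counts, and shares of wells have exact Clopper-Pearson 95% intervals. A count of 0 was set to a floor of 3 counts for ratios. With 1 library per group there are no replicates, so no test was made, no p-value is given, and each difference compares libraries, not conditions. Genes at least 2-fold apart were counted among genes with a mean CPM of at least 10 over both libraries.

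The named genes of each comparison are the 12 highest and the 12 lowest by log2 ratio with 5 CPM added to both sides, among genes with a mean CPM of at least 20, a count in at least 10% of wells of the higher library, no more than 25% of the counts of that library from a single well, and the same direction in the mean of per-well CPM and in the share of wells with a count. Pseudogene-like, Rik, mitochondrial and ribosomal protein symbols were left out of that choice, and Ino80 and members of the fixed lists may be named as list members. A gene chosen by this rule is not reported here. For each of the 31 gene lists and 12 cell type marker lists, the median log2 ratio was taken over members with a mean CPM of at least 5. Where at least 5 members were measured, the median was given a percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries; medians at or beyond the 2.5 and 97.5 percentiles are described below. The list of mitochondrially encoded genes used the total over all genes and has no percentile. These lists, the named-gene rule, the filters and most of the alternatives were fixed before the data were examined.

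Of the 51 distinct named genes, 14 have exons that overlap another annotated gene, 12 on the opposite strand (Agpat2, Dab2ip, Gt(ROSA)26Sor, Klhl9, Mybphl, Myh7, Myl4, Nmrk2, Nppa, Uck2, Usp2 and Zfp346) and 2 on the same strand (Mir22hg and Scd2). Their values may include reads of the neighbour and are uncertain. Hba-a1, Hba-a2, Hbb-bs, Hspa1a, Hspa1b and Bglap3 have near-identical copies, between which the counting could have split or dropped reads, and are uncertain for that reason.

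The comparison step was tested on simulated counts for the real genes with 200 changed genes per comparison, 50 at each fold. For day 2 against day 1, run on 4262 genes, 50 of 50 genes were recovered within 0.1 log2 at 2-fold, 4-fold and 0.25-fold and 49 of 50 at 0.5-fold. For day 3 against day 1 on 4262 genes and day 3 against day 2 on 4563 genes, 50 of 50 were recovered at each of these folds. The simulated counts were Poisson draws for genes at 20 CPM or more in the earlier library. The median shift of the unchanged genes was subtracted before scoring, which the real comparisons do not do. Recovery was therefore nearly fixed in advance, and it does not measure errors of scaling, spread between wells or duplicate reads. Alternatives covered the denominator, median-of-ratios size factors, the mean over wells, well and gene filters, all kept wells, wells thinned to 30000 counts, clustering settings, the compartment without atrial-like wells, and wells with 25 to 35% mitochondrial counts. The thinning depth was set after the depths had been seen, and the last pair of alternatives was chosen after the data had been seen. Bands of Ino80 CPM per well, under 100 and from 1000, were also chosen after the distribution had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.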

Results

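Heart cells of tamoxifen-treated mice were profiled by single-well RNA sequencing after 1, 2 and 3 days, with 1 library per day. The series title names Myh6-MCM, a tamoxifen-inducible Cre driven by the cardiomyocyte myosin promoter, together with floxed Ino80, whereas the genotype labels read INO80_OE and the design speaks of induction of Ino80. Ino80 is the ATPase subunit of the INO80 chromatin remodelling complex. The day 3 library carries 2 genotype labels, INO80_OE and Ctrl, and no file assigns its wells to either, so it was analysed as a mixture and every day 3 value below is that of the mixture. The tables held 1232, 1063 and 1099 wells with total counts of 487461107, 452070922 and 484369736 on days 1, 2 and 3. The median count per well was 316120, 349795 and 360693, and the median number of detected genes was 3249, 3639 and 3891. The cardiomyocyte compartment, on which the comparisons rest, held 582, 630 and 882 wells.

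Outside the compartment, wells fell into clusters with the markers of other cell types. Clusters named fibroblast-like took 12%, 11.9% and 7.33% of kept wells on days 1, 2 and 3, and macrophage-like wells took 7.92% (95% interval 6.47 to 9.57), 7.65% (6.12 to 9.42) and 7.97% (6.43 to 9.74). Endothelial-like wells took 31.1% (28.5 to 33.8), 17.9% (15.7 to 20.4) and 1.10% (0.569 to 1.91). Over the same libraries the endothelial markers inside the compartment stood at 0.214, 0.261 and 0.619 of their level in endothelial-like wells. In the day 3 library, with only 12 such wells, they separated least from the compartment, so the endothelial shares cannot be compared. Smaller classes were erythroid-like wells at 1.06%, 2.27% and 1.28%, neutrophil-like wells at 0.163%, 0.567% and 1.01%, and mesothelial-like wells at 0.245%, 0.189% and 0.549%. Atrial-like wells, led by Sln, Myl7, Mybphl and Myl4, numbered 21 on day 1 and 4 on day 3, with 0 of 1059 kept wells on day 2, which allows a share of up to 0.348%. The compartment without them took 45.8% (43.0 to 48.6), 59.5% (56.5 to 62.5) and 80.4% (77.9 to 82.7). These shares depended on the clustering: with 1000 variable genes the day 1 compartment without atrial-like wells took only 4.65%. Atrial-like wells, which the comparisons keep in, then took 38.6%, so 4.65% is not the share of wells that a comparison would use. On day 2 atrial-like wells took 1.04%, endothelial-like wells 10.1% and erythroid-like wells 0.944% in that setting. With wells of at least 5000 counts and 1000 genes, endothelial-like wells took 3.59%, erythroid-like wells 1.23% and the compartment 75.7% on day 2. Wells were chosen by imaging on every day, which can set these shares.

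**Figure D1:**
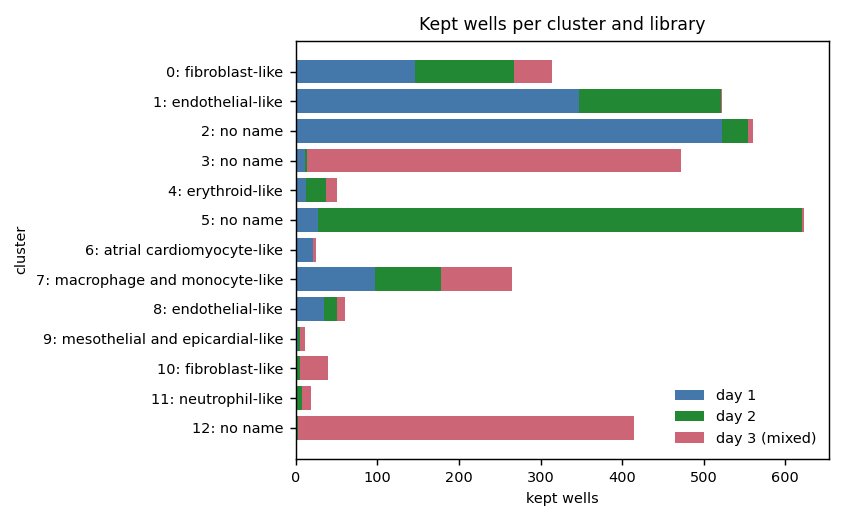
Kept wells per cluster (vertical axis, cluster number and name) as stacked counts of wells (horizontal axis), coloured by library. Cluster 2 was almost wholly day 1 (523 wells), cluster 5 almost wholly day 2 (593 wells), and clusters 3 and 12 held 458 and 411 wells of day 3, whereas the macrophage-like cluster 7 drew 97, 81 and 87 wells from the 3 libraries.

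Compartment wells of the 3 libraries fell into different clusters, none of which, apart from the atrial-like cluster, had enough markers for a name. The day 1 compartment was mostly cluster 2, that of day 2 was mostly cluster 5, and that of day 3 was mostly clusters 3 and 12; each comparison below is therefore between these clusters. They belong to the compartment by exclusion, not by cardiomyocyte markers: cluster 2 was led by the lymphocyte genes Trbc2 and Ccl5, cluster 5 by the immunoglobulin genes Igkc and Igha, cluster 3 by Gpr22, with Pln among its leading genes, and cluster 12 by Sprr1a and Bglap3, with the atrial gene Bmp10 among them. Trbc2 and Ccl5 were found in only 4.98% and 12.7% of day 1 compartment wells, and a single well gave 50.2% and 82.2% of their counts there. With 5 CPM added to both sides, ventricular cardiomyocyte markers stood at a median log2 ratio of 0.10, 0.01, 0.42 and −0.37 to all other wells in clusters 2, 5, 3 and 12. The share of mitochondrial counts in the compartment had a median of 40.7% (quartiles 36.6 to 45.1) on day 1, 43.6% (27.4 to 49.4) on day 2 and 21.3% (18.7 to 26.3) on day 3. Cardiomyocyte transcripts were abundant in every class: macrophage-like wells held Myh6, the main cardiac myosin heavy chain, at 11337, 9939 and 10197 CPM, against 13710, 12622 and 11669 CPM in the compartment.

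Ino80 was the first gene examined, as a check of the labels. Its level in the compartment was 2851 CPM (95% interval 2843 to 2860) on day 1, 4941 CPM (4930 to 4951) on day 2 and 1191 CPM on day 3. The day 2 library was therefore higher than the day 1 library by 0.79 log2 units, whereas the mixed day 3 library was at a log2 ratio of −1.26 to day 1 and −2.05 to day 2. The day 3 level averages unlike wells: those of cluster 12 stood at 2991 CPM, near the day 1 level, and those of cluster 3 at 28.8 CPM. These ratios thus do not show a fall in every well. Without a library labelled Ctrl alone, the check does not settle which manipulation was made. Ino80 (ENSMUSG00000034154.15) lies on chromosome 2 at 119373042 to 119477687 in mm10, and gene-level counts do not tell an added copy from the endogenous transcript. A count was found in 99.8%, 100% and 96.6% of compartment wells, and in 99.8%, 100% and 71.5% once wells were thinned to 30000 counts, which left out 13, 3 and 8 shallower wells. In macrophage-like wells Ino80 stood at 2446, 3864 and 1068 CPM, with a count in 100% of wells in every library, at median depths of 314580, 354016 and 350859 counts against 350998, 354394 and 361534 in the compartment. Among wells with 25 to 35% mitochondrial counts (85, 130 and 136 wells), the day 2 to day 1 ratio was smaller, at 0.14 log2 units.

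Within libraries, the spread of Ino80 over wells differed. The median per well was 2545 CPM on day 1 (quartiles 1598 to 3853) and 5187 CPM on day 2 (2678 to 7324). On day 3 the median was 110 CPM with quartiles of 15.7 and 2687 CPM, and 437 of 882 wells lay under 100 CPM, 46 between 100 and 1000 CPM and 399 at 1000 CPM or above. On days 1 and 2 only 5 of 582 and 0 of 630 wells lay under 100 CPM.

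**Figure D2:**
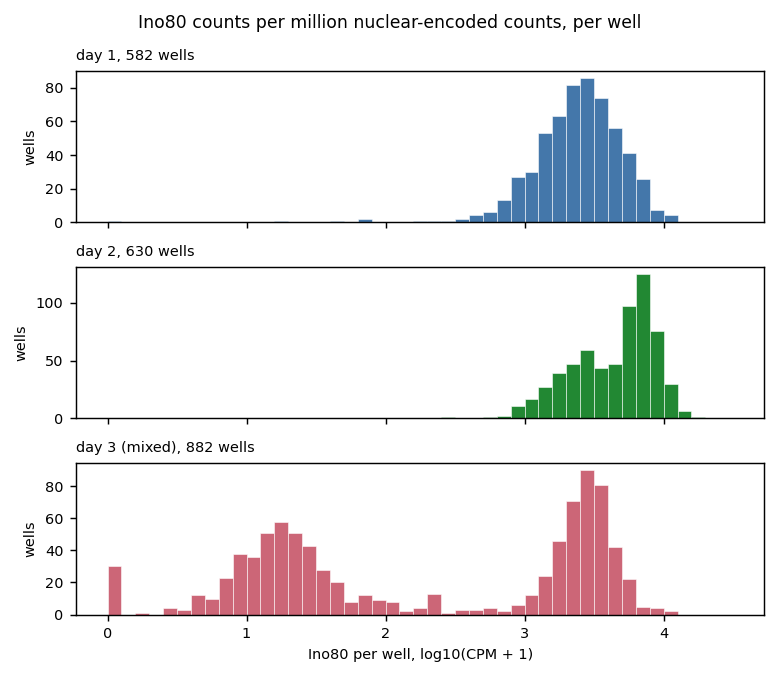
Histograms of Ino80 per compartment well, as log10 of CPM plus 1 (horizontal axis), with the number of wells on the vertical axis and a panel for each library. Of the day 1 and day 2 wells, 522 and 614 lie at 1000 CPM or above, whereas the mixed day 3 library has a low and a high range, with 437 wells under 100 CPM and 399 wells at 1000 CPM or above.

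The comparison of day 2 with day 1 followed the libraries labelled INO80_OE over the first interval. Among the genes with the largest differences on the higher side, Nfe2l2, the transcription factor of the antioxidant response, went from 48.4 to 149 CPM (log2 ratio 1.62, 95% interval 1.58 to 1.66), and Srxn1, which encodes sulfiredoxin, from 24.4 to 92.1 CPM (1.92, 1.86 to 1.97). Of the oxidative stress list 14 of 20 members were higher (median 0.25, within the percentile bounds). Rcan1, a feedback inhibitor of calcineurin, went from 53.1 to 173 CPM, and Tfrc, the transferrin receptor, from 12.9 to 61.4 CPM. Atrial genes were lower, with Sln (sarcolipin) at 3945 and 73.1 CPM and Myl7 (atrial regulatory light chain) at 1845 and 44.0 CPM. Nmrk2, a nicotinamide riboside kinase, was at 271 and 74.5 CPM, and Nr4a2, an orphan nuclear receptor, at 62.1 and 12.5 CPM.

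The other named genes of this pair included Lmcd1, a LIM domain cofactor (log2 ratio 2.09), Adamts1, a secreted metalloprotease (1.80), Uck2, a uridine-cytidine kinase (1.85), and Tnnt3, the fast skeletal troponin T (2.39), on the higher side. On the lower side were Agpat2, an enzyme of phosphatidic acid synthesis (−1.67), Trp53inp1 (−1.59), Kcnip2, a subunit of the transient outward potassium channel (−1.41), and the atrial markers Myl4 (−3.59), Nppa (−3.61), Dkk3 (−3.29), Stard10 (−2.35) and Sbk2 (−2.42). Among the 24 named genes the widest counting interval, that of Dkk3, was 0.10 log2 units to each side. Counts inside the 21 atrial-like wells of day 1 gave only part of the difference in atrial genes. Leaving these wells out does not remove any RNA of theirs in other wells, so their full part is not known. Without atrial-like wells Sln was still at −4.28, Myl7 at −4.10, Myl4 at −2.61, Nppa at −2.60 and Dkk3 at −2.12. Sln and Myl7 had a count in 99.3% and 99.0% of day 1 compartment wells, against 31.3% and 42.1% on day 2. A single well gave 54.8% and 36.6% of their day 2 counts. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs were higher at 3.14, 3.65 and 3.32, but at 1.16, 1.26 and 1.02 over all kept wells, where erythroid-like wells are included.

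In all, 285 genes were at least 2-fold higher and 116 at least 2-fold lower on day 2 among 6426 measured genes, so 71.1% of the genes apart were higher. That split was 48.5% with median-of-ratios size factors (164 higher, 174 lower). The median gene was at 0.13, and list medians are also given relative to the median of all genes measured for lists, which was 0.13. Of the 29 gene lists with a percentile, 4 lay above the 97.5 and 4 below the 2.5 percentile of matched random lists. For lists of genes drawn independently 0.725 would be expected each way. Members of a fixed list can vary together and some lists share genes, so the excess over 0.725 is a description only. None of these 8 changed direction under either other scaling. The cell type marker lists were counted apart, and of these the atrial (median −3.59) and fibroblast markers lay below the 2.5 percentile.

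Among the gene lists with a percentile, cytoskeletal and intercalated disc genes stood highest, with 23 of 26 members higher and a median of 0.56, which was 0.43 above the background. Examples were Tubb4b and Tuba4a, tubulin genes, at 103 and 222 CPM and at 167 and 348 CPM, and Ctnna1, alpha-catenin, at 174 and 314 CPM. Of the fetal and stress program 16 of 22 members were higher, with a median of 0.47, although the mean was −0.09 because of the atrial members. Ankrd1, a stretch-responsive ankyrin repeat protein, was at 536 and 1122 CPM, Nppb, the B-type natriuretic peptide precursor, at 212 and 527 CPM, and Acta1, skeletal alpha-actin, at 1168 and 2372 CPM. Heat shock genes had 14 of 18 members higher (median 0.43), with Bag3 at 126 and 310 CPM, Hsp90aa1 at 340 and 709 CPM and Hspb8 at 220 and 435 CPM. Extracellular matrix genes had 16 of 20 members higher (median 0.47), among them Col4a1 at 108 and 180 CPM and Timp1 at 8.89 and 23.1 CPM, while the fibroblast markers as a list had a median of −0.24 and Dcn (decorin) was at 160 and 72.2 CPM.

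Lipid metabolism stood on the lower side. Of the fatty acid oxidation genes 21 of 26 were lower, with a median of −0.20, which was −0.33 relative to the background; Fabp3, the cardiac fatty acid binding protein, was at 4502 and 2898 CPM, Slc27a1, a fatty acid transporter, at 176 and 91.7 CPM, and Ppargc1a, a coactivator of mitochondrial biogenesis, at 49.4 and 25.3 CPM. PPAR target and ketone genes had 11 of 16 members lower (median −0.17), including Pdk4 at 66.9 and 39.2 CPM and Plin5 at 164 and 99.7 CPM. Nuclear genes of oxidative phosphorylation had 41 of 60 members lower, with a median of only −0.08 that became 0.014 in wells with 25 to 35% mitochondrial counts. All 8 measured mitochondrially encoded genes were higher on day 2 on the all-gene scale (median 0.25). Nuclear retained RNAs had 4 of 5 members lower (median −0.51), with Malat1 at 5884 and 3305 CPM. Sarcomere genes split evenly, with 13 higher and 13 lower, and Flnc (filamin C) at 155 and 363 CPM beside Myom2 at 341 and 197 CPM. These differences have no replicate check.

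The mixed day 3 library was set against day 1 as the last and first time points. Genes higher in the mixture can come from a part of it. Gja1, Fhl2 and Pln were among the leading genes of cluster 3, whose day 3 wells had Ino80 at 28.8 CPM. Sprr1a, Bglap3 and Prr13 were among those of cluster 12, whose day 3 wells had Ino80 at 2991 CPM. The differences below are therefore not a time course of wells alike in Ino80. A pair of cell contact genes was higher on day 3: Gja1, a gap junction connexin, went from 22.7 to 149 CPM (log2 ratio 2.71, 95% interval 2.66 to 2.76), and Cdh2, N-cadherin, from 13.8 to 90.01 CPM (2.70, 2.64 to 2.77). Sprr1a, a small proline-rich protein induced under stress, was at 0.508 and 60.3 CPM (log2 ratio 6.89), but a single well gave 89.2% of its 74 day 1 counts, and the ratio was 5.04 as the mean over wells and 4.97 after thinning. Lgals3, galectin-3, was at 11.5 and 96.2 CPM, Angptl4, an inhibitor of lipoprotein lipase, at 5.41 and 55.5 CPM, and Fhl2, a LIM domain protein of the sarcomere, at 73.9 and 357 CPM. On the lower side were Esr1 (estrogen receptor alpha, whose ligand-binding domain is part of the MerCreMer fusion) at 510 and 40.0 CPM and Gt(ROSA)26Sor, a transcript of the locus commonly used for transgenes, at 91.5 and 13.7 CPM. Igfbp5, a binding protein of insulin-like growth factors, was at 272 and 46.9 CPM, and Myh7, the slow myosin heavy chain of the fetal heart, at 386 and 99.5 CPM.

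Other named genes on the higher side were Prr13 (log2 ratio 3.31), Bglap3, an osteocalcin-related gene with 65.6% of its day 1 counts from a single well (5.03), AC121802.1 (2.84) and the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, at 3.15, 3.43 and 3.23. Over all kept wells these 3 were at −0.04, −0.10 and 0.06, which turns the direction of the first pair. On the lower side were Zfp346 (−3.03), Nr4a2 (−2.72), Scd2, a stearoyl-CoA desaturase (−2.54), Pygo1, a Wnt pathway coactivator (−2.07), Usp2, a deubiquitinase (−1.80), and the atrial genes Sln (−2.35), Myl7 (−2.13) and Mybphl (−2.54). Without atrial-like wells the last 3 were at −1.09, −0.96 and −1.10. The widest counting interval, that of Sprr1a, was 0.34 log2 units to each side, and the next widest was 0.21.

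Here 297 genes were at least 2-fold higher and 353 at least 2-fold lower among 6149 measured, so 45.7% of the genes apart were higher. That share was 87.4% when mitochondrial counts were included in the total (529 higher, 76 lower) and 59.3% with median-of-ratios size factors (388 higher, 266 lower). The median gene was at −0.11, against 0.29 with mitochondrial counts in the total, and the background of the lists was at −0.13. Of the gene lists, 7 lay beyond the percentile bounds on the higher side and 1 on the lower side, and none of these 8 changed direction under either other scaling. Of the marker lists, the endothelial markers lay above the bounds and the atrial (median −1.42), fibroblast and pericyte and smooth muscle markers below. The median mitochondrial share of the same wells was 40.7% on day 1 and 21.3% on day 3.

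The gene list on the lower side was the INO80 complex, with 9 of 11 members lower and a median of −0.70, which was −0.57 relative to the background; with mitochondrial counts in the total the median was −0.12. Its members included Actr8 at 42.0 and 25.02 CPM and Mcrs1 at 15.3 and 9.39 CPM beside Ino80 itself, whereas Ruvbl1, an AAA ATPase shared with other complexes, was at 15.5 and 20.1 CPM. The fetal and stress program was highest among gene lists with a percentile, with 18 of 22 members higher and a median of 0.99, or 1.12 above the background, and of 0.31 among members with a mean CPM of at least 50. Ankrd1 was at 536 and 2056 CPM, Nppb at 212 and 600 CPM, and Uchl1, a neuronal deubiquitinase, at 8.66 and 47.6 CPM, whereas Myh7 and the atrial members were lower. Calcium handling genes had 18 of 22 members higher (median 0.37), among them Pln, phospholamban, at 96.2 and 351 CPM, Slc8a1, the sodium-calcium exchanger, at 44.5 and 173 CPM, and Camk2d at 23.8 and 59.3 CPM.

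Cytoskeletal and disc genes had 19 of 25 members higher (median 0.50), with Pkp2 (plakophilin 2) at 43.0 and 124 CPM and Pdlim5 at 235 and 507 CPM. Cardiac transcription factors had 14 of 21 members higher (median 0.35), such as Mef2c at 39.9 and 96.1 CPM, Tbx20 at 10.01 and 25.3 CPM and Prox1 at 21.7 and 42.5 CPM. Heat shock genes had 12 of 18 members higher (median 0.28), with Hspb1 at 691 and 2202 CPM and Hspa1a at 65.9 and 234 CPM. Of the p53 targets 8 of 14 were higher (median 0.29), with Cdkn1a at 408 and 508 CPM and Gadd45g at 63.1 and 134 CPM, and of the extracellular matrix genes 11 of 19 (median 0.30), with Timp1 at 8.89 and 51.6 CPM. Markers of other cell types moved in different directions in the same wells: 18 of 19 endothelial markers were higher (median 0.49), 11 of 12 fibroblast markers were lower (−0.73) and 8 of 10 pericyte and smooth muscle markers were lower (−0.63). Over all kept wells, however, the endothelial markers Pecam1 and Fabp4 were lower on day 3, at 35.3 and 20.5 CPM and at 269 and 202 CPM. Endothelial-like wells, 31.1% of kept wells on day 1 and 1.10% on day 3, are left out of the compartment, which can set the direction there. The 8 measured mitochondrially encoded genes were all lower (median −0.56). Immediate early and dissociation genes, such as Jun at 106 and 56.9 CPM, had 14 of 21 members lower (median −0.19, within the percentile bounds), but the median was 0.18 with mitochondrial counts in the total.

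**Figure D3:**
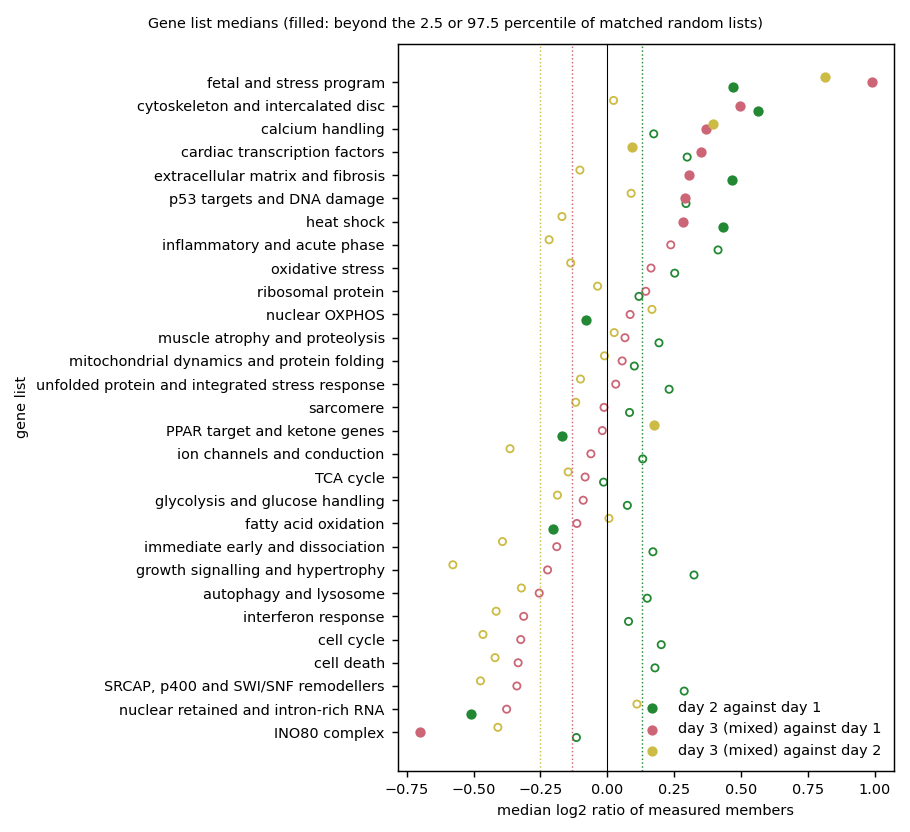
Median log2 ratio of each gene list with a percentile (horizontal axis) for the 3 comparisons, with lists on the vertical axis, zero as a solid line and the median of all measured genes of each comparison as a dotted line. Filled points lie beyond the 2.5 or 97.5 percentile of matched random lists; the fetal and stress program is filled in every comparison (0.47, 0.99 and 0.82), and the INO80 complex only for day 3 against day 1 (−0.70).

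Day 3 against day 2 set the mixed library against the last single-label library. Here too the genes higher in the mixture led different clusters: Gpr22 and Gja1 were among the leading genes of cluster 3. Sprr1a, Prr13, Ankrd2 and Mir22hg were among those of cluster 12. Ino80 itself was among the named genes on the lower side, at 4941 and 1191 CPM (log2 ratio −2.05), with Esr1 at 425 and 40.0 CPM and Gt(ROSA)26Sor at 118 and 13.7 CPM. Igfbp5 (246 and 46.9 CPM), Myh7 (367 and 99.5 CPM) and Alpk3, a muscle alpha-kinase (328 and 90.5 CPM), were also lower. On the higher side, Gpr22, an orphan receptor found in heart, was at 3.12 and 68.1 CPM (4.45, 95% interval 4.32 to 4.58), Angptl4 at 4.86 and 55.5 CPM, and Gja1 at 29.7 and 149 CPM. Sln, Myl7, Myl4 and Nppa were higher by 3.40, 3.26, 2.29 and 2.83 log2 units, and by 3.20, 3.13, 2.20 and 2.79 without atrial-like wells. A single well gave 54.8% and 36.6% of the day 2 counts of Sln and Myl7.

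The other genes named on the higher side were Sprr1a (3.38), Lgals3 (2.84), Prr13 (2.35), Ankrd2, a muscle ankyrin repeat protein (3.05), and Mir22hg, a microRNA host transcript (2.32). On the lower side were Zfp346 (−2.63), Scd2 (−2.37), Armcx4 (−2.35), Nfil3, a basic leucine zipper factor (−1.95), Dab2ip (−2.09) and Klhl9 (−2.03). Counting intervals reached 0.13 log2 units to each side at most, for Gpr22. In wells with 25 to 35% mitochondrial counts several ratios were smaller, with Lgals3 at 0.84, Prr13 at 0.90, Angptl4 at 1.96, Sprr1a at 1.80, Armcx4 at −0.91 and Dab2ip at −0.85. Others were larger there, among them Gpr22 at 6.39, Sln at 4.66, Mir22hg at 3.44 and Esr1 at −4.26.

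Here 191 genes were at least 2-fold higher and 558 at least 2-fold lower among 6298 measured, so 25.5% of the genes apart were higher. That share was 79.3% with mitochondrial counts in the total (349 higher, 91 lower) and 60.2% with median-of-ratios size factors (333 higher, 220 lower), so the main direction of this count turned with the scaling. The median gene was at −0.24, against 0.14 with mitochondrial counts in the total, and the background of the lists was at −0.25.

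The 4 gene lists beyond the percentile bounds were all on the higher side, as were the atrial (median 2.56) and endothelial markers among the marker lists. The fetal and stress program had 16 of 22 members higher (median 0.82, or 1.07 above the background), including Ankrd1 at 1122 and 2056 CPM and Fhl1 at 70.8 and 131 CPM. Of its other members, Rcan1 was at 173 and 62.8 CPM and Acta1 at 2372 and 1309 CPM. Its higher members also included the atrial genes Nppa, Myl4 and Myl7, at 2.83, 2.29 and 3.26 log2 units. Calcium handling genes had 17 of 22 members higher (median 0.39), with Pln at 103 and 351 CPM and Trdn, triadin, at 451 and 1115 CPM. That list holds the atrial gene Sln, at 3.40. PPAR target and ketone genes had 10 of 16 members higher (median 0.18), with Ucp3 at 3.56 and 12.9 CPM and Plin2 at 118 and 190 CPM, although the median was −0.03 with wells of at least 5000 counts and 1000 genes. Cardiac transcription factors had a median of only 0.09, with 12 of 22 members higher, and of −0.05 over all kept wells. The median was 0.33 with mitochondrial counts in the total, 0.34 with median-of-ratios size factors and 1.48 in wells with 25 to 35% mitochondrial counts. Of the INO80 complex 10 of 11 members were lower (median −0.41, within the percentile bounds, against a background of −0.25), but the median was 0.04 with mitochondrial counts in the total. Nuclear genes of oxidative phosphorylation had 51 of 60 members higher (median 0.17, within the percentile bounds, and −0.10 in wells with 25 to 35% mitochondrial counts), and the 8 measured mitochondrially encoded genes were lower (median −0.75). The endothelial markers stood at 0.20 in the compartment, from which endothelial-like wells, 17.9% of day 2 and 1.10% of day 3 wells, are left out. Over all kept wells, Pecam1 was at 24.4 and 20.5 CPM and Fabp4 at 265 and 202 CPM. The differences of this comparison have no replicate check.

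**Figure D4:**
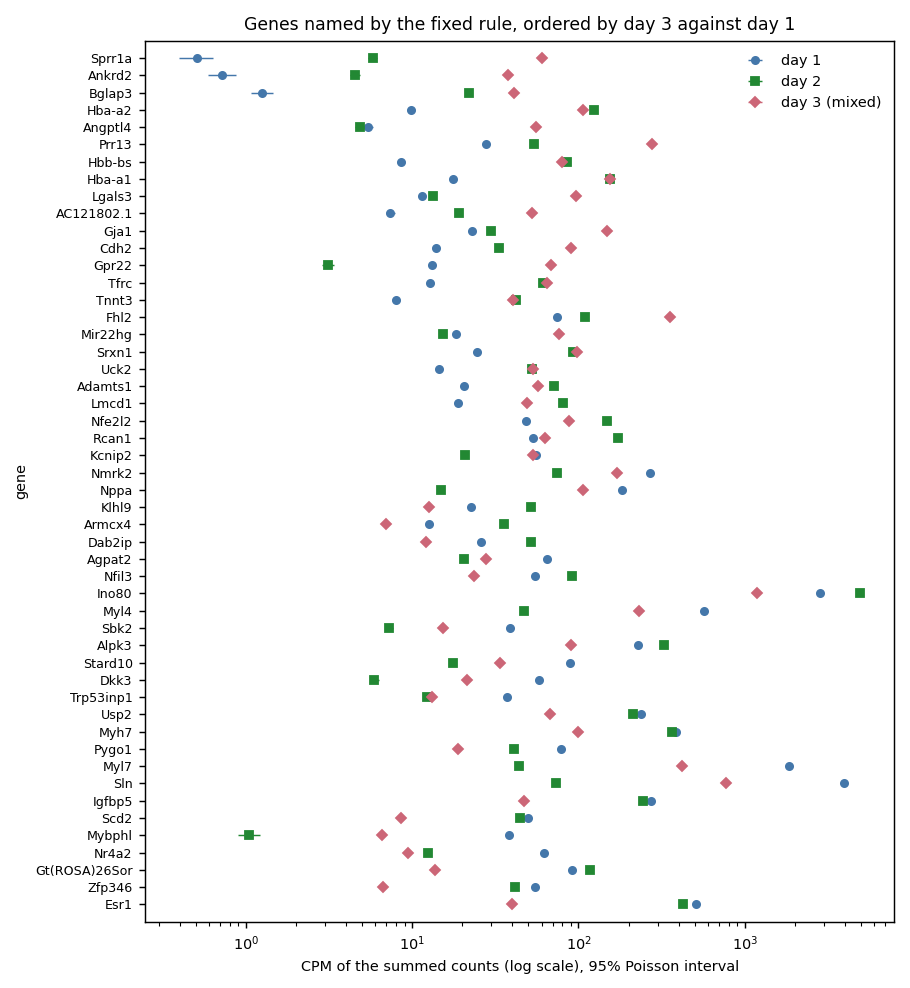
CPM of the summed counts (horizontal log axis) of genes named in the comparisons (vertical axis), ordered by the ratio of day 3 to day 1, with a marker for each library and bars for the 95% Poisson interval. Sprr1a stands at the top at 0.508, 5.81 and 60.3 CPM and Esr1 at the bottom at 510, 425 and 40.0 CPM, while the atrial genes Sln and Myl7 are lowest on day 2.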

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

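No test in this part was chosen after its result was seen, since the values below come from features outside the comparisons, set against the limit of 3 counts that a count of 0 allows; no separate control library was analysed here. EGFP, the green fluorescent protein, was counted 744, 627 and 539 times on days 1, 2 and 3, in 59, 61 and 51 kept wells (4.82%, 5.76% and 4.67%), and a single well gave up to 202, 182 and 145 of these counts. The 3xFlag tag was counted 19, 19 and 23 times, in 10, 11 and 9 wells. ERCC spike-ins were counted 307, 247 and 270 times, in 9.55%, 12.2% and 12% of kept wells. SIRV spike-ins were counted 78, 220 and 90 times, in 5.06%, 15.3% and 5.86% of kept wells. The labels name neither a reporter, a tag nor spike-ins. EGFP stood at 1.53, 1.39 and 1.11 CPM of all counts.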

How the results depend on the processing

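The compartment without atrial-like wells and the wells with 25 to 35% mitochondrial counts were chosen after the results had been seen, and the other alternatives were planned. Ino80 kept its direction in all 27 alternative values, of which 24 moved beyond the counting interval. Of 870 alternative gene list medians 115 changed sign: 4 of the 200 for lists beyond the percentile bounds, and 111 of the 670 for lists within them. Of 639 values of the other named genes 442 moved and 2 reversed. With all genes in the CPM total, 250 genes were apart for day 2 against day 1 (186 higher, 64 lower), 529 were higher and 76 lower for day 3 against day 1, and 440 were apart for day 3 against day 2 (349 higher, 91 lower). With median-of-ratios size factors, 164 were higher for day 2 against day 1, and 333 higher and 220 lower for day 3 against day 2. With a mean CPM of at least 50, fewer genes were measured, and 58 (44 higher, 14 lower), 134 (87 higher, 47 lower) and 153 (67 higher, 86 lower) were apart in the 3 comparisons. With wells of 25 to 35% mitochondrial counts, which leaves fewer wells, 1328 (737 higher, 591 lower), 1613 (946 higher, 667 lower) and 1338 (755 higher) were apart. The Ino80 log2 ratios for day 2 against day 1, day 3 against day 1 and day 3 against day 2 were 0.81, −0.89 and −1.69 with all genes in the total, 0.66, −1.15 and −1.81 with median-of-ratios, 0.84, −1.05 and −1.89 as the mean over wells, 0.75, −1.30 and −2.05 with wells of at least 5000 counts and 1000 genes, and 0.87, −1.13 and −2.00 over all kept wells. They were 0.83, −1.05 and −1.88 after thinning, 0.76, −1.29 and −2.05 without atrial-like wells, and 0.14, −1.17 and −1.31 in the mitochondrial window. Over all kept wells Hba-a1 and Hba-a2 reversed to −0.044 and −0.096 for day 3 against day 1, and the cardiac transcription factors reversed to −0.048 for day 3 against day 2. The PPAR target and ketone genes reversed to −0.033 with the stricter well filter and to −0.0060 with a mean CPM of at least 50 for day 3 against day 2, and nuclear OXPHOS reversed to 0.014 in the mitochondrial window for day 2 against day 1. With 1000 variable genes, the compartment without atrial-like wells took 4.65% and 68.7% of wells on days 1 and 2, and atrial-like wells took 38.6% and 1.04%. Endothelial-like wells then took 35.6%, 10.1% and 1.92% on days 1, 2 and 3, and erythroid-like wells 0.944% on day 2. With wells of at least 5000 counts and 1000 genes, the day 2 compartment took 75.7%, endothelial-like wells 3.59% and erythroid-like wells 1.23%. At Leiden resolution 1 mesothelial-like wells took 0% on each day. Apart from the fewer genes or wells named above, the cause was not tested. No paired analysis was possible because each day has 1 library. Depth limited Sprr1a most among the named genes, with 0.34 log2 units of counting error to each side at 0.508 CPM on day 1, where 89.2% of its 74 counts came from a single well. Its log2 ratio for day 3 against day 1 was 6.89, but 5.04 as the mean over wells and 4.97 after thinning.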

Other observations

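Of the tests in this part, those of the mitochondrial share of the day 3 clusters, of cross-talk and of cardiomyocyte RNA in the same well were chosen after the results had been seen; those of the genotypes and of the genes apart between days 3 and 1 were written down before. Immunoglobulin transcripts marked the day 2 library. Igkc, the kappa light chain constant region, was found in 52.1% of day 2 compartment wells, against 0.515% on day 1 and 0.794% on day 3. A single well gave 98.2% of its day 2 compartment counts. It was also found in 54.3% of macrophage-like, 54.0% of fibroblast-like and 48.9% of endothelial-like wells of day 2, at 7.19, 4.06 and 3.61 CPM. Igha, the alpha heavy chain constant region, was found in 25.6% of day 2 compartment wells, again with 98.1% of its counts from a single well. These genes were picked after their values were seen.

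Other features of the wells were not part of a comparison. A fibroblast-like cluster led by Timp1, Postn and Col3a1, genes of activated matrix production, held 34 wells of day 3, 4 of day 2 and 1 of day 1, whereas the larger fibroblast-like cluster, led by Dcn and Gsn, held 46, 122 and 146. With 1 library per day, a cluster mostly of 1 library cannot be called a cell type apart from that library. Several ion channel genes, picked after their values were seen, were lower in the day 3 mixture than on day 1: Kcna5, a potassium channel, was at 15.1 and 3.63 CPM, Kcnh2 at 18.2 and 5.09 CPM, and Scn4b, a sodium channel subunit, at 13.6 and 4.11 CPM. Kcnd2 was instead at 11.3 and 26.4 CPM, and Fgf13, a modulator of sodium channels, at 5.41 and 33.0 CPM. The list of ion channels as a whole had 7 of 19 members higher (median −0.06), but its direction turned with the scaling: the median was 0.32 with mitochondrial counts in the total, 0.05 with median-of-ratios size factors and 0.53 in wells with 25 to 35% mitochondrial counts.

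Day 3 compartment wells fell mostly into 2 clusters of about equal size, 458 and 411 wells, and a hypothesis is that these reflect the 2 genotypes named in the label. Clustered again without Ino80, Esr1 and Gt(ROSA)26Sor, the 2 clusters held 444 and 408 wells, with Ino80 at 29.99 and 2995 CPM, a ratio of 99.9, where a ratio of at least 4 had been set for the hypothesis and under 1.5 against it. Esr1 stood at 0.844 and 101.2 CPM, and Gt(ROSA)26Sor at 1.93 and 32.4 CPM. The mitochondrial share separated the 2 clusters poorly, with an area under the ROC curve of 0.658, which argues against RNA damage seen in that share as the whole cause. No well was assigned to a genotype, and other differences between the 2 clusters, such as separate cell isolations if there were any, remain untested.

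Macrophage-like wells held cardiomyocyte markers close to the compartment's level, at 0.769, 0.806 and 0.895 of it on days 1, 2 and 3. Cross-talk from the whole pool, if it made up the same share of every well's counts, would bring macrophage markers into compartment wells to the same degree. Their fraction of the pool there was at most 0.231 of that of the cardiomyocyte markers in macrophage-like wells. For these wells that argues against cross-talk of this even kind only. The test cannot decide on cross-talk whose share differs between wells, because the RNA of a well was not measured. For fibroblast-like wells the same value was at most 0.486, just under the 0.5 set against cross-talk. For erythroid-like wells it was 0.0470, 0.192 and 0.524, which is under that bound on days 1 and 2 only. For endothelial-like wells it was 0.502, 0.704 and 1.01, within the 2-fold set for cross-talk, which stays open there. The day 3 value is no support for it: with 12 endothelial-like and 882 compartment wells, the pool is mostly the compartment, which largely sets that value. A cardiomyocyte or its RNA in the same well stays open: the median total count of macrophage-like wells was at least 0.896 of that of compartment wells, but those of fibroblast-like and endothelial-like wells were at least 0.861 and 0.790 of it, and reads do not measure the RNA of a well, so the total decides nothing. No biological explanation was tested, and the low levels of Igkc over day 2 wells leave weaker cross-talk open.

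Genes at least 2-fold apart between day 3 and day 1 could reflect the mitochondrial share of the wells, which differed between the libraries. Among wells with 25 to 35% mitochondrial counts, 57.1% of these genes were still at least 2-fold apart in the same direction. That lies between the 50% set for this explanation and the 80% set against it, with 85 and 136 wells left, so the mitochondrial share and the day of the library cannot be told apart for these genes. The day and the genotype mixture stay open, as untested.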
